A study of Mus musculus with 18 samples.

How the data were processed

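RNA from mouse palate at embryonic day 15.5 was measured on 18 Affymetrix 1-colour arrays, 6 in each of 3 groups: anterior palate of controls carrying the floxed receptor allele, posterior palate of such controls, and posterior palate of mutants that also carried K14-Cre, a recombinase driven by a keratin promoter that is active in epithelial cells. Groups and replicate numbers were taken from the sample titles. The series design text gives 5 samples per group where the labels list 6, and all 6 were used. It also places mutants and controls in separate litters. Nothing in the labels says which arrays come from which animals, or whether a sample is 1 embryo or a pool, so p-values measure the spread between these samples.

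Values were used as deposited. The authors made them with RMA (background correction, quantile normalization between arrays and summary per probe set), per the submitters' processing notes, which give no version. The deposited values are on a log2 scale, without centring per gene, and cover 45101 probe sets. Scanner files and detection calls were not used here, so a level near the lower end of the range may be background. RMA forces the arrays towards a common distribution, so a change shared by most genes would be removed. Array number limits the precision.

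Probe sets were named through the platform annotation table, and their Entrez gene numbers were matched to a RefSeq table of mouse genes (18032 genes matched, and no symbol changed). Of 45101 probe sets, 34958 had 1 symbol, 932 had several and 9211 were unlisted; the 64 control probe sets were left out of the tests. Among probe sets with 1 symbol, the brightest over all 18 arrays stood for its gene, which gave 18193 genes. No filter on dim genes was applied.

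Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) by lmFit and eBayes, 2-sided, in 1 fit over the 3 groups with 15 residual degrees of freedom and no covariate. The genotype contrast was mutant posterior minus control posterior, and the region contrast was control posterior minus control anterior. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes. Of 29 gene lists fixed before the data were examined, 27 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. List members that were not measured by a probe set with 1 symbol (34 of 504) were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

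Genes named in the text followed a rule written at the same time. They are a fixed set of receptor, WNT, muscle, palate patterning and sex-linked genes; the 10 largest called changes in each direction among genes whose groups did not overlap; and, from each list, up to 4 called members with the largest change, or up to 2 members with the smallest p where none was called. Predicted genes were passed over. Genes outside the rule are marked as chosen after their values were seen.

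Equal replicate numbers were checked for pairing before calls of the fits were compared. Deviations from the group means of anterior and posterior control arrays with equal numbers correlated across genes at 0.111 to 0.430, above 0.1 in all 6 pairs, and the numbers were taken to pair these samples. Between mutant and control posterior arrays only 2 of 6 pairs exceeded 0.1. The pairing for region therefore comes from the data, not from the labels, and stays an assumption. Control arrays with equal numbers also share the sets described below, which could give such correlations without a shared embryo. Only 3 of 6 posterior control arrays correlated best with the anterior array of their own number.

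The fit was tested on simulated data over 18193 genes, with independent noise and 1 spread per gene shared by all arrays. For genotype it recovered 61.2% of genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 97.0% of those changed by 2, with 2.37% of calls false. For region the shares were 56.7%, 88.1% and 100%, with 4.12% of calls false. The real groups differ in spread, with a median SD over genes of 0.233 in mutant and 0.128 in control posterior arrays. Real arrays also correlate within the sets described below (consensus correlation 0.262 with 4 sets). The simulation leaves both out, so its shares need not hold for these data.

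Alternatives were other choices of probe set, a filter on dim genes, other scalings, other variance models, array weights, the 12 arrays of the compared groups alone, replicate blocks, stricter thresholds, covariates for sex, epithelium and muscle, and leaving out each array. Spike-in controls showed sets of arrays that the labels do not name, and fits by these sets were added after seeing the data. A pseudocount was not needed, since the values are already logarithms.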

Results

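Gene expression was measured in whole palate tissue at embryonic day 15.5, when the palate is forming, in 6 control anterior, 6 control posterior and 6 mutant posterior samples. The mutants lacked Tgfbr2, a receptor for TGF-beta ligands, in cells with K14-Cre activity, so the deletion is expected in epithelium and not in mesenchyme or muscle. The stated question was how loss of this signal in epithelium affects the exchange between palatal epithelium and muscle fibres. Array means lay between 6.26 and 6.37 on the log2 scale. Labelling spike-in controls averaged 10.2 ± 0.82 in control anterior, 10.3 ± 0.75 in control posterior and 7.90 ± 0.55 in mutant arrays (mean ± SD, n = 6 each), and no mutant array reached the lowest control array.

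**Figure D1:**
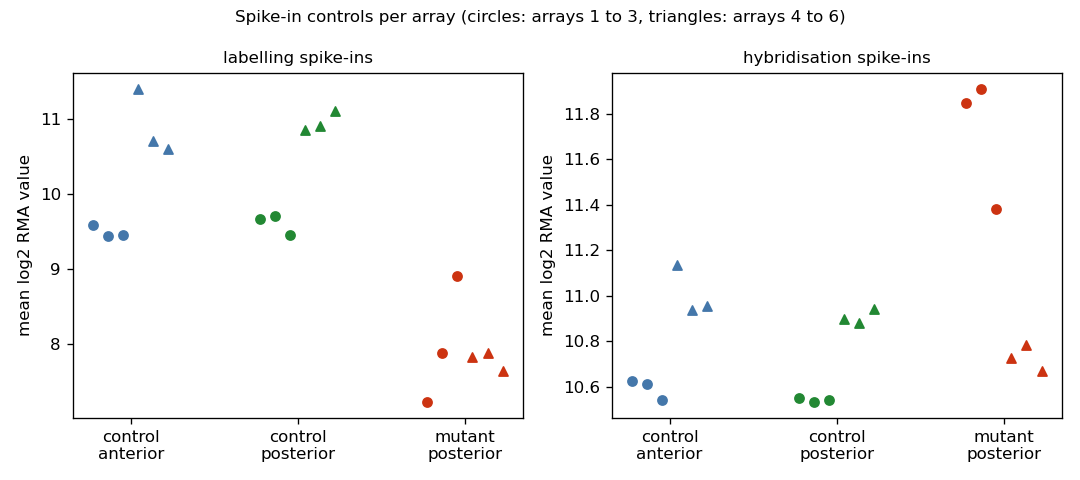
Mean log2 value of the labelling (left) and hybridisation (right) spike-in controls, 1 point per array, in the 3 groups. Circles are arrays 1 to 3 and triangles arrays 4 to 6; the highest mutant array for labelling lies at 8.91 and the lowest control array at 9.44.

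The brightest probe set of Tgfbr2 itself read higher in mutant than in control posterior palate, at 11.01 ± 0.27 against 10.46 ± 0.20 (SD, n = 6 each), a log2 difference of 0.55 (SE 0.13, adjusted p = 0.00879, limma). Its other probe sets differed by 0.24 (adjusted p = 0.131) and -0.10 (adjusted p = 0.503) when every probe set was tested. The call of the brightest probe set was lost with control arrays 1 to 3 only (adjusted p = 0.317, limma). The deletion is limited to epithelial cells within whole tissue and the position of the probes relative to the deleted part was not examined, so these values do not check the labels.

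The genotype comparison asked which genes differ between mutant and control posterior palate. Of 28 genes of stratified epithelium 14 were higher in the mutants, led by the stress keratin Krt6b, which was 12.8-fold higher (log2 3.68, SE 0.70, adjusted p = 0.00257), and by Sprr1a, a cornified envelope precursor, which was 7.27-fold higher (log2 2.86, SE 0.51, adjusted p = 0.00158). The secreted WNT antagonists Dkk4 and Dkk1 were 5.6-fold and 2.41-fold higher, and 7 of 11 tendon genes, 3 of 19 cartilage genes and 2 of 14 bone genes were higher, where 13.5% of all genes were called in either direction. Embryonic globin Hbb-y was 7.65-fold lower (log2 -2.93, SE 0.26, adjusted p = 1.88e-06). In all, 2449 of 18193 genes were called, 1407 higher and 1042 lower in the mutants, and 238 of them differed at least 2-fold. With the 2 compared groups alone 1572 genes were called. The 6 values of each group did not overlap for 6.55% of all genes, where independent arrays without a difference would give 0.216%. Arrays correlate within sets that lie within genotypes, as described below, so this gap does not exclude differences between sets.

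Among 28 measured genes of stratified epithelium differentiation, 14 rose and none fell (15 when adjusted over the list alone). Besides Krt6b and Sprr1a these included Krt13, a keratin of mucosal epithelium (log2 2.38), and the envelope genes Sprr3 (2.36) and Cnfn (2.24). The cysteine protease inhibitor Csta1, outside that list, rose by 2.41. None of 23 basal and simple epithelial genes was called (0 when adjusted over the list alone). Krt14 differed by -0.29 (adjusted p = 0.522) and Cdh1, the epithelial cadherin, by -1.07 (adjusted p = 0.0871). Without mutant array 1 Cdh1 differed by -0.58 and was called (adjusted p = 0.0372, with 0.00481 to 0.558 over its alternatives). Krt14 differed by -0.05 in that fit (adjusted p = 0.906). The mean of the basal and simple list was 8.67 in mutant array 1 and 10.3 or more in each other mutant array.

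Of 17 measured WNT inhibitors 3 rose (4 when adjusted over the list alone), namely Dkk4 (log2 2.49, SE 0.56, adjusted p = 0.00798), Dkk1 (1.27, SE 0.38, adjusted p = 0.0346) and Sost (1.26, SE 0.22, adjusted p = 0.00148). Camera did not call this list (adjusted p = 0.111, and 0.786 with an estimated correlation), while fry did (adjusted p = 0.0346). Dkk4 exceeded the control mean in 5 of 6 mutant arrays. WNT beta-catenin targets gave 1 call among 14, Nkd1 (log2 0.59), and 1 when adjusted over the list alone. The list had a median of 0.04 and a mean of -0.02. Nkd1 was not called with the mean of its probe sets (adjusted p = 0.121). Axin2 differed by 0.04 (adjusted p = 0.909) and Lef1 by 0.17 (adjusted p = 0.417). Of 18 WNT ligands none was called (0 when adjusted over the list alone). Among TGF-beta ligands, receptors and SMADs 2 of 19 rose, Tgfbr2 and the coreceptor Tgfbr3 (log2 0.86), and 4 rose when adjusted over the list alone. Among 18 TGF-beta target genes 3 rose and 1 fell (4 and 1 when adjusted over the list alone), with Timp3, a metalloproteinase inhibitor, at 0.74 and the cell cycle inhibitor Cdkn2b at -1.24.

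Of 41 sarcomere genes 4 rose (3 when adjusted over the list alone), while 40 had a positive difference, with a median of 0.74 and a mean of 0.79 (camera adjusted p = 4.07e-05, and adjusted p = 0.786 with an estimated correlation). Those that rose included muscle creatine kinase Ckm (log2 2.36, SE 0.56, adjusted p = 0.00986), the calcium release channel Ryr1 (1.36) and the calcium pump Atp2a1 (1.23). The myogenic factors Myod1 and Myog differed by 0.35 (adjusted p = 0.494) and 0.36 (adjusted p = 0.617). Of 17 muscle regulators 3 rose, Myf6 (1.55), Mef2c (0.60) and Mef2a (0.55), and Six4 fell by 1.48 (3 and 1 when adjusted over the list alone). Six4 differed by -2.73 with mutant arrays 1 to 3 only and by -0.22, not called, with 4 to 6 only. FGF signalling genes gave 4 calls among 19, all higher, with Fgfr4 at 0.93 and Fgf10 at 0.57 (4 when adjusted over the list alone). Among 21 BMP signalling genes 4 rose (4 when adjusted over the list alone), the inhibitor Chrd by 0.46, and among 13 SHH signalling genes 3 rose and 1 fell (3 and 1 when adjusted over the list alone), the coreceptor Cdon rising by 0.87. The sarcomere list mean ran from 8.06 to 10.6 over the 6 mutant arrays and from 8.05 to 9.13 over the control posterior arrays. Its highest value was that of mutant array 1, which had the lowest mean of basal and simple epithelium.

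Of 11 tendon genes 7 rose (7 when adjusted over the list alone), among them Tnmd, a tendon membrane protein (log2 1.40, SE 0.30, adjusted p = 0.00614), the proteoglycan Dcn (0.88) and the transcription factors Egr2 (0.88) and Egr1 (0.72). Egr1 also belongs to the immediate early and heat shock genes, of which 3 of 15 rose (4 when adjusted over the list alone; the list was not called, with adjusted p = 0.335). Of 19 cartilage genes 3 rose (3 when adjusted over the list alone): Col10a1, the collagen of hypertrophic cartilage (2.77), Comp (1.80) and Col11a2 (1.23). Of 14 bone genes 2 rose, Dmp1 (2.54) and Phex (2.24), both expressed by osteocytes, and 3 rose when adjusted over the list alone. Cell cycle genes gave 6 lower and no higher calls among 25 (7 when adjusted over the list alone), with Ccne2 at -0.77, Cenpa at -0.54 and Birc5 at -0.39.

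Of 8 anterior and 8 posterior mesenchyme genes none was called for genotype (0 of the anterior, and 1 higher and 2 lower of the posterior, when adjusted over each list alone), with differences of -0.66 for Meox2 (adjusted p = 0.233), -1.21 for Tbx22 (adjusted p = 0.139), -0.61 for Barx1 (adjusted p = 0.0643), 0.48 for Msx1 (adjusted p = 0.592) and -0.09 for Shox2 (adjusted p = 0.883). Without mutant array 1, where Msx1 read 9.83 (5.86 to 7.64 in the others), the differences were -0.40 for Meox2, -0.73 for Tbx22, -0.39 for Barx1 and -0.08 for Msx1, none of them called. With mutant arrays 1 to 3 only, Meox2 (-1.58), Tbx22 (-2.14) and Barx1 (-0.94) were called, with adjusted p = 1.37e-05, 0.00703 and 0.00999, each the lowest over its alternatives (highest 0.900, 0.853 and 0.380). With 4 to 6 only they differed by 0.27, -0.28 and -0.29 and were not called. Of 13 erythroid genes 2 rose and 2 fell (2 and 3 when adjusted over the list alone), of 20 macrophage and leukocyte genes 3 rose and 2 fell (4 and 2), and of 13 nasal epithelium genes 1 rose and 4 fell (2 and 4). Hbb-y and Hba-x (-1.40) fell, Ank1, a membrane skeleton protein of red cells and muscle, rose (0.75), and the complement gene C1qb (-0.68) and leukocyte antigen Cd52 (-1.17) fell. Secretory nasal genes Bpifa1 (-1.68) and Reg3g (-1.60) fell while lactotransferrin Ltf rose (1.60). Other genes with the largest changes were the mast cell tryptase Tpsab1 (2.68) and Clec3b (2.62), both higher. Gt(ROSA)26Sor (-3.63), Ang (-2.93), Zfp874a (-2.85), Sult1d1 (-2.41), Kdf1 (-2.24), Svopl (-2.21), Dnph1 (-1.96), Rpgrip1 (-1.83) and Rsl1 (-1.81) were lower.

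**Figure D2:**
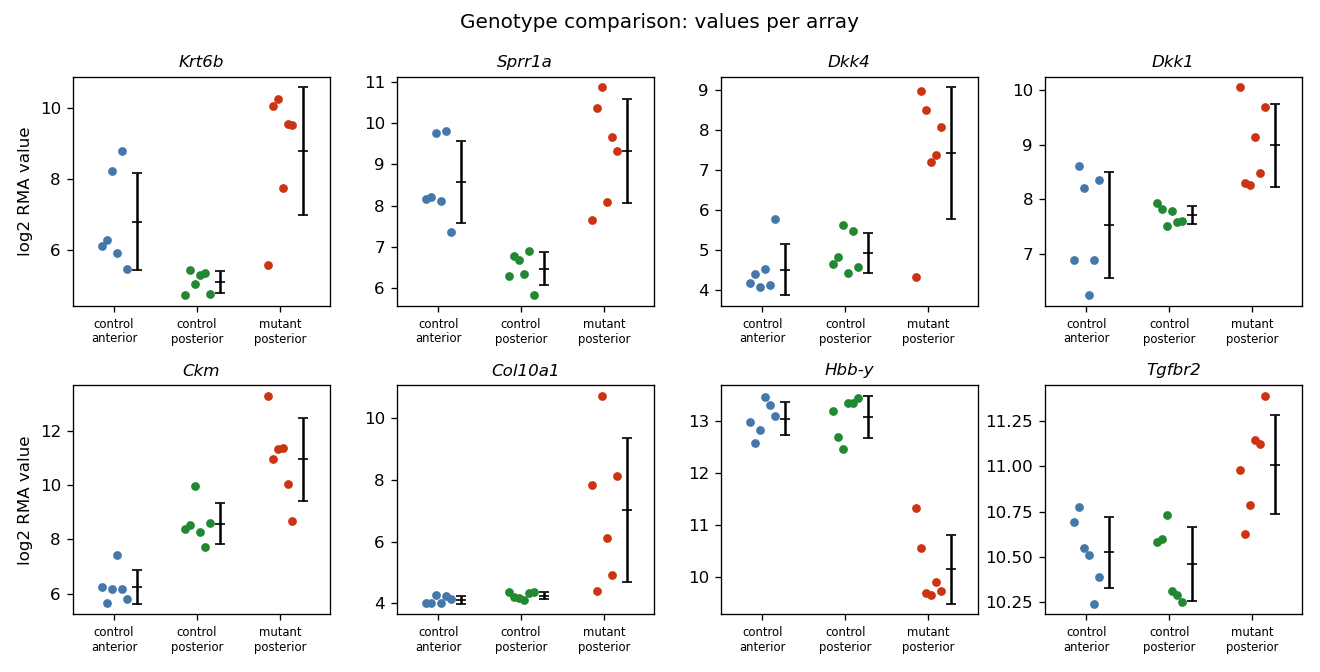
Log2 RMA values of 8 genes, 1 point per array and 6 arrays per group, with the group mean and SD as a bar beside the points. Dkk4 is raised in 5 of 6 mutant arrays, and Hbb-y is lower in all 6 than in any control posterior array.

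With camera, 7 of 27 lists were called for genotype: sarcomere (adjusted p = 4.07e-05), stratified epithelium (6.97e-05), tendon (0.00161), cartilage (0.00451) and osteogenesis (0.0370) were shifted up, and cell cycle (0.000889) and basal and simple epithelium (0.0170) were shifted down. With an estimated correlation camera called none (1 list had an unadjusted p under 0.05): tendon had adjusted p = 0.383 and the other 6 had adjusted p = 0.786. Fry called 6 lists. Stratified epithelium and cell cycle (adjusted p = 0.0346 each, fry) and tendon (0.00048) were among the 7 of camera. WNT inhibitors, FGF signalling and TGF-beta ligands, receptors and SMADs (0.0346 each) were not. Fry did not call sarcomere (0.124), cartilage (0.124), osteogenesis (0.137) or basal and simple epithelium (0.499). Hybridisation spike-ins parted arrays 1 to 3 from 4 to 6 within each genotype. Labelling spike-ins parted them in controls but overlapped in mutants. Clustering of the spike-ins put mutant array 3 apart from arrays 1 and 2, and no cluster held both genotypes. Arrays 1 to 3 and 4 to 6 of each genotype were taken as 4 sets, so none of these held both genotypes. With the 4 sets as a random block, added after seeing the data, 588 genes were called. Dkk4 (adjusted p = 0.0991, with 3.84e-05 to 0.219 over its alternatives), Dkk1 (0.209, with 0.0128 to 0.274), Krt6b (0.0518, with 2.73e-06 to 0.0965) and Ckm (0.0840, with 0.000356 to 0.308) were not. That block ended 25 calls of named genes, with adjusted p from 0.0518 to 0.258; the others were Krt13, Col10a1, Comp, Col11a2, Dmp1, Tnmd, Ryr1, Atp2a1, Ank1, Myf6, Mef2c, Six4, Six3 (log2 -0.82), Nkd1, Timp3, Hba-x, Bpifa1, Reg3g, Ltf, Fgfr4 and Fgf10. It also ended the calls of the osteogenesis (0.0778, with 0.00115 to 0.786) and basal and simple epithelium lists (0.0671, with 0.000232 to 0.786). With mutant arrays 4 to 6 only, 11 lists were called, all shifted up, and neither cell cycle (0.138, with 2.69e-05 to 0.786) nor basal and simple epithelium (0.251) was; with 1 to 3 only, osteogenesis, cartilage and tendon were not. The share of higher genes among calls was 57.5% as deposited but 40.5% after median centring, and 1592 or 1512 genes were called without control posterior array 4 or 5. Leaving out 1 array ended some calls, with the highest adjusted p for Dkk1 (0.0749) and Six4 (0.0698) without mutant array 1, for Bpifa1 (0.0923) without control posterior array 2, for Myf6 (0.0844), Mef2c (0.0808), Fgf10 (0.0714), Ank1 (0.0720), Comp (0.0562), Ryr1 (0.0584) and Atp2a1 (0.0624) without array 5, and for Col11a2 (0.0734) and Ltf (0.0672) without array 6. Of 18 such fits, 15 ended the call of Bpifa1, 8 that of Dkk1, 7 those of Six4, Myf6, Mef2c, Fgf10 and Col11a2, 5 that of Ank1, 3 those of Comp and Ltf, and 1 those of Ryr1 and Atp2a1. Of 54 named calls besides Tgfbr2, 39 were called with each set of mutant arrays alone. Ckm, Ryr1, Atp2a1, Myf6, Six4, Col11a2, Ank1, Six3 and Fgfr4 were called with 1 to 3 only but not with 4 to 6 only, and Dkk1, Dmp1, Mef2c, Hba-x, Bpifa1 and Ltf the other way round. Both fits use the same control posterior arrays, so they are not independent replications. The 54 were also picked as calls over all 6 mutant arrays, which favours a call with each set. With control arrays 1 to 3 only, 48 of these 54 calls were lost, and with control arrays 4 to 6 only, 23 were lost.

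The region comparison asked which genes distinguish posterior from anterior palate in controls. Skeletal muscle genes were among the largest increases in posterior palate: Tnni1, slow troponin I, was 20.6-fold higher (log2 4.37, SE 0.45, adjusted p = 2.81e-05) and Myog, a myogenic transcription factor, 16.3-fold higher (log2 4.02, SE 0.41, adjusted p = 2.81e-05). The mesenchymal regulators Meox2 and Tbx22 were higher posteriorly, and Alx1, Msx1 and Shox2 were higher anteriorly. In all, 695 of 18193 genes were called, 309 higher and 386 lower in posterior palate, and 202 differed at least 2-fold. This fit shares its variance with the mutant arrays, whose median SD over genes was 0.233. It was 0.128 in control posterior and 0.152 in control anterior arrays. With the 2 compared groups alone, 2151 genes were called for region and 1572 for genotype. The order of the counts depends on the fit, so they do not show which comparison changes more genes. The anterior and posterior control groups did not overlap for 6.32% of all genes, where independent arrays without a difference would give 0.216%.

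Of 41 sarcomere genes 33 were higher in posterior palate and none lower (36 when adjusted over the list alone), including Myh3 (log2 4.32), Tnnc1 (4.23), Myh8 (4.03), Myl1 (3.93) and Ttn (3.91). Of 17 muscle regulators 8 were higher and 1 lower (13 and 2 when adjusted over the list alone): Myf5 (3.83), Myod1 (2.92) and the acetylcholine receptor subunit Chrna1 (2.78) were higher, and Pax3, a marker of muscle precursors and of other tissues that was chosen after its values were seen, was lower at -1.46 (adjusted p = 0.0371). The fusion factor Mymx (4.05), the calcium pump regulator Sln (3.92) and Tceal7 (4.37) were among the 10 largest increases.

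Anterior mesenchyme genes gave 4 lower calls among 8 (5 lower and 1 higher when adjusted over the list alone): Alx1 (log2 -3.59, SE 0.26, adjusted p = 7.89e-07), Msx1 (-2.86, SE 0.52, adjusted p = 0.00377), Shox2 (-2.40, SE 0.31, adjusted p = 0.000167) and Cyp26b1, which degrades retinoic acid (-1.35). Posterior mesenchyme genes gave 3 higher calls among 8 (4 when adjusted over the list alone): Meox2 (2.89, SE 0.35, adjusted p = 8.67e-05), Tbx22 (1.92, SE 0.53, adjusted p = 0.0489) and Hic1 (0.69). Barx1 differed by 0.77 (adjusted p = 0.0501). Of 12 HOX genes 3 were higher posteriorly, Hoxa2 (0.89), Hoxb2 (0.66) and Hoxa3 (0.29), and 5 were higher when adjusted over the list alone. Hoxa2 averaged 4.15 in posterior and 3.27 in anterior controls, and Hoxa3 5.73 and 5.45. These lie below the array medians, which averaged 5.77 and 5.75, so background may enter. Hoxb2 read 6.96 in control posterior array 3 and 5.75 to 6.05 in the others.

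Other posterior increases were the tendon genes Kera (3.03) and Thbs4 (1.68), the smooth muscle actin Acta2 (1.26), the BMP antagonist Grem1 (1.12), bone sialoprotein Ibsp (1.44) and complement genes C1qa (0.60) and C1qb (0.62). Tendon genes went both ways: of 11, 2 were higher and 1, Fmod, was lower (4 and 3 when adjusted over the list alone). Camera did not call the tendon list (adjusted p = 0.141). Lower in posterior palate were the enamel gene Ambn (-2.14), Sprr1a (-2.10), Serpinb7 (-2.01), Nat3 (-1.85), Gata3 (-1.81), Cpxm2 (-1.78), Six3 (-1.70), Col17a1 (-1.08), Fmod (-1.0), the WNT and BMP inhibitor Sostdc1 (-0.97), Bmp6 (-0.96) and Foxf1 (-0.69). Krt14 (-0.65, adjusted p = 0.187), Dkk1 (0.18, adjusted p = 0.842), Dkk4 (0.42, adjusted p = 0.732) and Tgfbr2 (-0.07, adjusted p = 0.821) were not called.

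**Figure D3:**
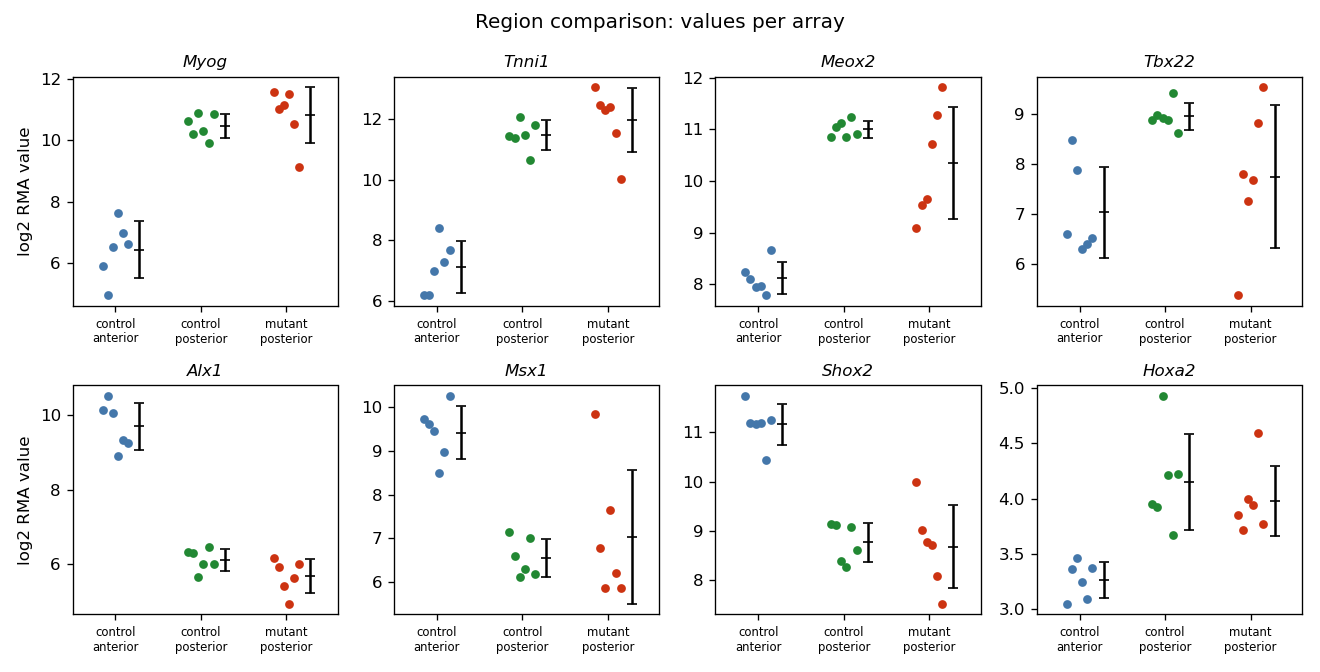
Log2 RMA values of 8 genes, 1 point per array and 6 arrays per group, with the group mean and SD as a bar beside the points. Myog, Tnni1, Meox2, Tbx22 and Hoxa2 are higher in control posterior than in control anterior arrays, and Alx1, Msx1 and Shox2 are lower.

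With camera, 9 of 27 lists were called for region. Sarcomere, muscle regulators and HOX genes, shifted up, were also called with an estimated correlation (adjusted p = 0.0326 each). Anterior mesenchyme (2.88e-05) was shifted down and posterior mesenchyme (0.0258) up, with adjusted p = 0.0513 and 0.477 with an estimated correlation. Basal epithelium (0.00333), stratified epithelium (0.00835) and SHH signalling (0.0295) were shifted down and macrophages (0.00539) up, and these 4 had adjusted p = 0.624 with an estimated correlation.

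In the 12 control arrays alone 2151 genes were called for region. With replicate numbers as a block added there, 3156 genes were called, 691 of them among the 695, and Barx1 (adjusted p = 0.00141, with 0.00102 to 0.658 over its alternatives) and Krt14 (0.00538, with 0.00538 to 0.975) were called as well, but not the lists SHH signalling (0.0529, with 0.00257 to 0.624) and posterior mesenchyme (0.0578, with 0.000134 to 0.477). The block over 18 arrays gave 677 calls and ended those of Tbx22 (0.0623, with 0.000574 to 0.737), Hoxa3 (0.0678, with 0.00131 to 0.531), Gata3 (0.0682, with 0.00108 to 0.720), Col17a1 (0.0518, with 0.000427 to 0.914) and Ibsp (0.0669, with 0.000943 to 0.577). Within sets, control arrays 1 to 3 gave 82 calls and 4 to 6 gave 16, with Myog at 4.77 and 3.28 (adjusted p = 0.00349 and 0.0512), Alx1 at -4.15 and -3.02 (0.000227 and 0.00181) and Meox2 at 2.91 and 2.87 (0.0649 and 0.127); the share of higher calls over all arrays was 44.5% as deposited but 71.3% after median centring. Leaving out 1 array ended some calls, with the highest adjusted p for Hoxa3 (0.0759) and Ibsp (0.112) without control anterior array 1, Hoxb2 (0.0615) without array 2, Gata3 (0.0979) without array 3 and Tbx22 (0.106) without array 4, and for Pax3 (0.0916), Col17a1 (0.115), Sprr1a (0.0728), Hic1 (0.0514) and Foxf1 (0.0510) without control posterior array 6. Of 18 such fits, 14 ended the call of Tbx22, 11 those of Col17a1 and Ibsp, 9 those of Pax3 and Gata3, 7 that of Hoxa3, 4 those of Hoxb2 and Sprr1a, and 1 those of Hic1 and Foxf1.

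**Figure D4:**
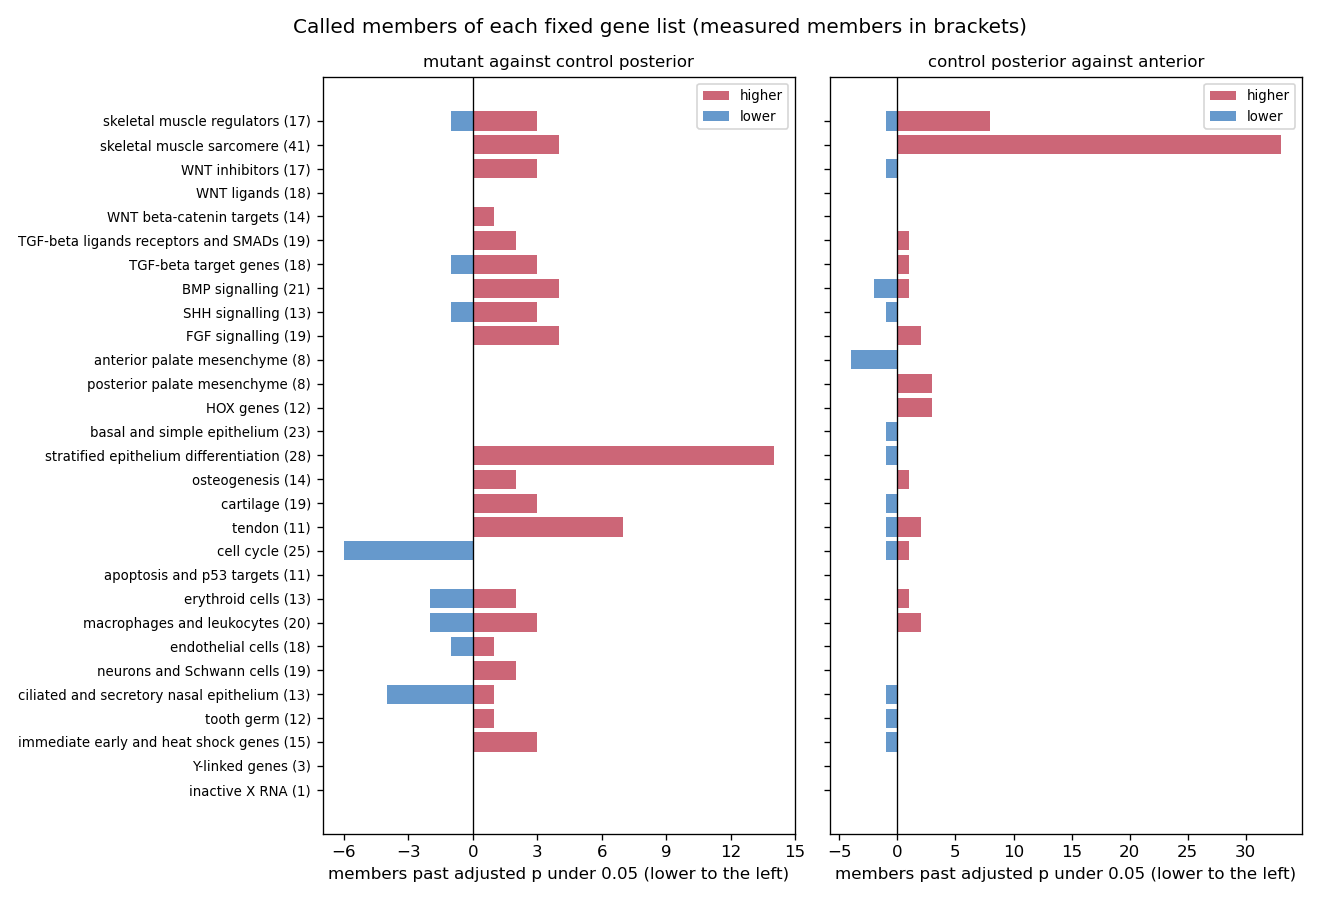
Number of members of each fixed list called higher (to the right) and lower (to the left) for genotype and for region, with the number of measured members in brackets. Stratified epithelium has 14 higher calls for genotype and sarcomere has 33 for region.

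The relation of both comparisons asked whether genes that distinguish the regions also differ by genotype. Across 18193 genes, which are not independent replicates, the log2 changes correlated at 0.117, where simulated unchanged groups of independent arrays sharing the control posterior arrays gave -0.257. With the pairing of control samples kept, by changing the sign of the deviations of samples with equal numbers together at random, unchanged groups gave -0.191 on average with 95% between -0.509 and 0.212, so 0.117 lies within the range of unchanged groups. The covariance was 0.0123, against -0.00578 in the first simulation and -0.00365 (-0.0109 to 0.00361) in the second, so it lies above the range of unchanged groups where the correlation does not. With the control posterior arrays split 3 and 3, the correlation had a median of 0.160 over 20 assignments (0.0641 to 0.251), and 0.137 (0.0456 to 0.247) with the anterior arrays of equal number split alike. Genes called higher in both numbered 46, where independent lists would share 23.9, and 68 genes were higher in the mutants and lower in posterior palate (29.9 for independent lists). Genes lower in the mutants numbered 13 among those higher in posterior palate (17.7 for independent lists) and 16 among those lower there (22.1); unchanged groups gave 0.02 shared calls on average. The numbers for independent lists leave out the shared control posterior arrays, so they are not the values without a shared change. The correlation over all genes was 0.0166 without mutant array 1 and 0.0621 without control posterior array 3, and 0.142 with control arrays 1 to 3 only against 0.0011 with 4 to 6 only; no set held both genotypes.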

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

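The tests of blood content, epithelial content, labelling and mutant array 1 were chosen after the results were seen. Of 313 groups of 6 values examined, 18 held an array far from the rest of its group, a rate of 5.75% where chance gives about 1 in 20. Mutant array 1 accounted for 6 of them: Barx1 read 8.81 (others 9.88 to 10.37), Ltf 5.80 (8.29 to 8.90), Mef2a 10.92 (10.27 to 10.43), the mean of basal and simple epithelium 8.67 (10.34 to 11.12), the mean of nasal epithelium 5.91 (7.47 to 8.33) and its median correlation with the other arrays 0.961 (0.977 to 0.986). Mutant array 3 was low for Birc5 at 10.23 (10.48 to 10.58) and for the cell cycle mean at 9.95 (10.11 to 10.20). Mutant array 2 was low for the endothelial mean at 7.42 (7.94 to 8.16), and mutant array 6 was high for Nkd1 at 8.0 (7.58 to 7.72). Control posterior array 6 was low for Col17a1 at 8.90 (9.74 to 9.93) and in its median correlation at 0.986 (0.990 in each other array), array 1 was low for C1qa at 9.16 (9.39 to 9.53), and array 3 was high for Hoxb2 at 6.96 (5.75 to 6.05) and for the HOX mean at 5.13 (4.88 to 4.92). Control anterior array 4 was low for Bmp6 at 7.75 (8.20 to 8.45), array 6 was high for Dkk4 at 5.80 (4.07 to 4.53), and array 2 was high for the cartilage mean at 8.67 (6.40 to 7.20).

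Mutant arrays 1 to 3 stood apart from 4 to 6, with array means of 6.35 to 6.37 against 6.28. Less epithelium may account for part of what sets mutant array 1 apart. Its basal and simple epithelium score lay 6.61 SDs below the mean of the other 5 mutant arrays, with all 23 members below each of them. That array also read high for Ambn at 7.63 (others 3.97 to 5.38) and Cma1 at 11.18 (7.63 to 9.02), picked after their values were seen. The score does not cover such genes and says nothing of arrays 2 and 3. Changes computed from arrays 1 to 3 and from 4 to 6 of each genotype, which share no array, correlated across genes at 0.271, between the 0.1 and 0.3 set beforehand as bounds, so set-specific processing as the whole of the genotype difference cannot be told apart from an effect of genotype. The rank correlation of these changes was 0.168, and 55.45% of all genes changed in the same direction in both. Labelling spike-ins were lower in mutants by a log2 difference of -2.38, as a labelling difference needs, but no set of arrays held both genotypes, so that difference cannot be told apart from genotype or litter either.

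The embryonic globins Hbb-y and Hba-x fell in the mutants (Hbb-bh1 differed by -1.0, adjusted p = 0.0957), while 14 of 28 stratified epithelial and 7 of 11 tendon genes rose (15 and 7 when adjusted over each list alone). Less blood is argued against, since the score of the red cell genes Alas2, Slc4a1 and Klf1 differed by 0.126 (95% interval -0.53 to 0.78), where embryonic globins differed by -1.78; dim genes and Ank1, also expressed in muscle, were left out of it, and without mutant array 1 the differences were -0.10 (-0.50 to 0.29) and -2.03. More epithelium as the whole of the rise is argued against, since the stratified score (0.97) moved apart from the basal and simple score (-0.33, 95% interval -1.24 to 0.57) by 1.31 (0.69 to 1.92), and by 1.12 (0.61 to 1.63) without mutant array 1, which alone gave the lower basal and simple mean. Later developmental stage of the mutant embryos stays open: 10 measured genes that fall as embryos mature differed by -0.0135 (95% interval -0.11 to 0.08), which just reaches the bound of -0.1 set beforehand. Dim genes were kept in this score. Lin28a, Lin28b, Trim71, Arid3b and Nr6a1 read below the median of every array and may be background. Such genes can hardly fall and draw the score and its interval towards no change. The genotype itself, and litter, stay open as untested explanations.

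Some of the largest single-gene differences may reflect sequence or isoform differences between the animals of the litters used. Among genes called at least 2-fold for genotype that had another bright probe set, 27 of 68 (39.7%) had one moving by under 0.25, against 2 of 31 (6.45%) for region, where both sides come from controls (Fisher's exact test, 1-sided p = 0.000396). This does not say which genes are affected, and an effect of genotype on isoforms stays open. Each control set lies on both sides of the region comparison, but no set held both genotypes. The excess for genotype therefore cannot be told apart from differences in processing or labelling between sets.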

How the results depend on the processing

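Fits by processing set and by subsets of arrays were chosen after seeing the data; the rest were planned. The cause of each change below was not tested, except where fewer arrays or a stricter threshold act by construction. Genotype calls (2449) were 4835 over all probe sets, 1572 with 2 groups only, 752 at 1.5-fold or more, 905 at an adjusted p under 0.01 and 1349 with the muscle covariate. They were 588 with 4 sets and 650 with 5 spike-in clusters as random block, 4986 with mutants 1 to 3 only (3318 with 4 to 6), 135 with controls 1 to 3 only and 1008 with controls 4 to 6 only. Region calls (695) were 3356 with array weights, 2151 with 2 groups only, 3156 with the replicate block in 12 control arrays, 361 at 1.5-fold or more, 251 at an adjusted p under 0.01 and 60 with the muscle covariate, which itself separates the regions. They were 1322 and 1586 with the random blocks, 2195 with mutants 4 to 6 only, 82 with controls 1 to 3 only, 16 with controls 4 to 6 only and 3118 with control set as a fixed factor. The replicate block over 18 arrays gave 2495 genotype calls (2206 shared with the 2449), and only 3 of 6 posterior control arrays correlated best with their own number; for region 571 of 695 calls were shared, and among named genes it changed no other call than those given for region. Genotype lists (7) were 0 with an estimated correlation, 11 (all up) with mutants 4 to 6 only and 4 with mutants 1 to 3 only; region lists (9) were 3 with an estimated correlation and 4 with fry. Tgfbr2 (0.55) did not reach 1.5-fold over all arrays, and was 0.34 with mutants 1 to 3 only (adjusted p = 0.0733) but 0.76 with 4 to 6 only (0.00143), and 0.37 with controls 1 to 3 only (0.317) but 0.73 with 4 to 6 only (0.021), over a range of 0.000807 to 0.317. Leaving out each array gave 1512 to 2735 genotype calls, 389 to 1213 region calls (without control posterior array 6 and without mutant array 1), 5 to 10 genotype and 8 to 12 region lists, 0.47 to 0.63 for Tgfbr2 and 0.0166 to 0.155 for the relation. Region calls without control anterior array 1 or 3, or control posterior array 2 or 4, were 442, 458, 450 and 437. With the muscle covariate Hic1 (-0.067) and Acta2 (-0.021) changed sign for region, as did the called lists basal epithelium, stratified epithelium and SHH signalling. Leaving out an array ended the call of 12 of 55 named genotype and 10 of 43 named region genes in at least 1 fit. It reversed none. Of the named genotype calls, 4 sets as random block ended 25, 2 groups only 13 and the muscle covariate 12. Controls 1 to 3 only ended 48 and controls 4 to 6 only 23. With controls 1 to 3 only, lost calls included Clec3b (adjusted p = 0.0707), Sprr1a (0.0887), Tpsab1 (0.107) and Sost (0.137). The share of higher calls moved with scaling for genotype (45.8% quantile, 47.3% 75th percentile) and region (57.9% and 71.0%). Signal over background was not used here, so dim genes are the least certain.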

Other observations

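Genes of mast cells and other features outside the fixed lists were examined, and the genes named here beyond Tpsab1 were chosen after their values were seen. In the mutants the fetal serum protein Afp was higher by 2.74 on the log2 scale (SE 0.51, adjusted p = 0.00221; mutant array 2 read 4.71 and the others 6.64 or more), as were the nuclear RNA Malat1 (1.68, SE 0.30, adjusted p = 0.00193) and the actin regulator Cap1 (2.18, SE 0.23, adjusted p = 1.53e-05). The neuropeptide Gal (-2.34, SE 0.43, adjusted p = 0.00205), the cell cycle inhibitor Cdkn2a (-1.26, SE 0.22, adjusted p = 0.00139) and the histocompatibility genes H2-K1 (-1.24, SE 0.28, adjusted p = 0.00785) and H2-D1 (-1.52, SE 0.46, adjusted p = 0.0352) were lower, the last 2 most in mutant array 6 (6.25 and 5.0). Pnrc2 (-2.29, adjusted p = 0.0248) read 7.26 to 7.52 in mutant arrays 1 to 3 and 11.1 to 11.3 in 4 to 6.

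The test of zinc finger genes, the subsets of the mast cell test and the removal of muscle-linked genes from the test of an anterior pattern were chosen after the results were seen. A hypothesis that mast cell genes are higher as a group in the mutants was tested on 11 genes, of which 2 rose, Tpsab1 and Mitf. Camera gave p = 0.00482 with the preset correlation and p = 0.142 with an estimated one, so the hypothesis stays open. Their mean was higher by 0.70 (exact permutation p = 0.00433, 2-sided), by 0.49 (p = 0.00649) without mutant array 1, where Cpa3 read 11.02 and Cma1 11.18 (8.0 to 9.46 and 7.63 to 9.02 in the others), and by 0.32 (p = 0.0173) without that array and Tpsab1, which had been seen before the test. A hypothesis that genes with a Zfp symbol are lower as a group was tested on 336 genes, of which 72 fell and 24 rose. Camera gave p = 8.23e-07, and p = 0.0166 with an estimated correlation; the direction held under quantile normalization, median centring and 75th percentile centring. For region, between controls, 6 of these 336 genes were lower and none higher, where camera gave p = 0.0014, and p = 0.101 with an estimated correlation. Litter and labelling remain confounded with genotype.

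A hypothesis that mutant posterior palate shifts towards the anterior pattern was tested on 653 genes called for region outside the muscle lists. With the control posterior arrays split, changes by genotype and by region correlated at a median of 0.369 (0.154 to 0.525 over 20 assignments), where such a shift needs a negative value. That test was planned, but its bound does not hold as an exclusion, since genes that follow the sarcomere mean within the control groups carry the correlation: without them (488 genes left) and with no sample number on both sides the median was 0.0858 (-0.0611 to 0.224). Relative to all genes, those higher in posterior palate had a median genotype change of 0.20 (0.03 without muscle-linked genes) and those lower there one of 0.06 (0.06). The hypothesis therefore stays open.

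Other groupings of the arrays into 6 and 6 were drawn to ask whether chance gives as many calls. For genotype, 1 of 100 groupings, the real one, gave 2449 genes, and the highest other gave 102. These groupings treat the arrays as independent. Arrays correlated within the 4 sets, however (consensus correlation 0.262), and the sets lie within genotypes. Groupings that mix the sets cannot say how many calls chance differences between sets would give, so they do not exclude chance for this count. With 4 sets as a random block 588 genes were called, but 2 sets per genotype are too few to settle it. For region, 1 of 100 gave 695 and the highest other gave 2; among the 32 groupings that part all 6 pairs, 1 gave as many and the highest other gave 0. List counts are different: 66 of 100 groupings gave at least the 7 lists called for genotype, with up to 15, and 28 of 100 gave at least the 9 called for region, with up to 15. Chance is therefore not excluded for the number of lists called by camera with a preset correlation.

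Xist and Y-linked transcripts separated most arrays by sex. Control array 1 of both regions and mutant array 1 held both, with Xist at 10.07, 10.69 and 8.13 and a Y-linked mean of 6.97, 6.65 and 7.61. The labels do not say whether a sample is 1 embryo or a pool. Among the others, the Y-linked mean was above 8 in control arrays 2, 3 and 6 of both regions and in mutant array 5.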
